A study of Zea mays with 4 samples.

How the data were processed

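RNA from internodes of 2 WS and 2 CCR mutant samples was hybridised to the Affymetrix maize array, 1 array per sample, with 20 µg of amplified RNA per array, per the labels' protocols. Plants were grown at 25 °C by day and 22 °C by night with 16 h of light and 8 h of dark, per the labels' protocols. The values deposited by the authors were made with GCRMA, per the submitters' processing notes; its version is not given in the sources used here. GCRMA corrects background by probe base composition, normalizes arrays by quantiles and gives 1 value per probe set. The deposited values are taken as log2: the table does not state the base of the logarithm, and the range of 1.12 to 14.1 fits GCRMA's usual log2 output. Of 17734 probe sets, 2007 carry more than 2 decimals in the table and the rest at most 2. Samples were grouped by their labels, and all 4 columns of values were mapped.

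The deposited values were not normalized again. Control probe sets (179) were left out. The design fixed before the data were examined named only the AFFX controls; the 66 probe sets for reporter genes were also left out, as controls of the same kind, and used to gauge background. A probe set was tested if its log2 value was at least 4 on at least 2 of the 4 arrays, which left 11085 of 17555. Each was fitted with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; the value is CCR mutant minus WS. The fit had 2 residual degrees of freedom and a prior of 1.70. The median difference of the tested probe sets was -0.05. Confidence intervals are at 95% and come from the same fit.

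The test was tried on simulated data with known answers for this comparison, with 11085 probe sets and 10 simulations. It recovered 46.7% of changes of 1 on the log2 scale, 76.3% of changes of 2 and 91.5% of changes of 4, and 4.29% of its calls were false. The camera test found a list of 15 probe sets shifted by 0.5 in 10 of 10 simulations and an unshifted list in 0 of 10. The simulated noise was normal and independent between probe sets, with the real residual SDs shuffled over them. In the real data the estimated correlation between the genes of a list reached 0.73. The shares and counts from the simulations therefore need not hold for the real arrays.

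Gene names come from the platform annotation of 2007, which pairs 1452 probe sets with 1 gene, 1 with several and 16281 with none; the last are unnamed here, not without a gene. Of its 1109 gene identifiers, 1060 were found in the RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0 and 976 had a name. No genome build is given for the array in the sources used here, so no coordinates are printed. Of the tested probe sets 994 had 1 gene, for 839 genes, of which 735 had a name.

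Gene lists were tested with limma's camera with a preset correlation of 0.01, on 1 probe set per gene (that with the highest mean), for lists with at least 5 tested genes, with Benjamini-Hochberg adjustment over the lists. The 25 lists were fixed before the data were examined. Their membership was corrected by gene name once the annotation had been read, before any difference between the groups was computed. A list of MADS-box genes and a list of other inflorescence genes were added after the results were seen. Two-sided fry tests ask whether the genes of a list move on balance 1 way, or in either direction, without comparing them with other genes.

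The rule for named genes was fixed before the data were examined. It takes all CCR probe sets. It takes the 12 largest rises and 12 largest falls among passing probe sets with 1 named gene whose arrays do not overlap between the groups, or, if fewer than 10 pass, the 10 named genes with the smallest p, given as values; uncharacterized genes are passed over. It takes up to 4 passing genes per list, or the 1 gene with the smallest p. As no passing probe set had a gene, the rule's provision for unnamed probe sets (the 2 largest rises and the 2 largest falls) was applied to them, with 1 more where the measured rises were equal. Genes beyond this rule (MCM7, KN-1, lg3, PAL1, 4CL, CAD2, opr5, expB4, Aox, gst14, M7, m27, zap1, m4, m15, zmm19, m26, m20 and the other genes of the closing section) were chosen after their values were seen.

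The alternatives tried were no filter, a filter at 6, a variance trend, robust variances, repeated quantile normalization, median-centred arrays, a replicate block, leaving out each array, leaving out probe sets whose names end in _s_at or _x_at, other variance models, a minimum difference of 1 and Bonferroni. For the lists they were other set tests and the mean of a gene's probe sets.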

Results

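Transcript levels were measured on Affymetrix maize arrays in young stacked internodes of plants at the stage of 6 to 7 leaves. The labels describe 2 CCR mutant samples, in which cinnamoyl-CoA reductase (CCR), an enzyme of lignin precursor synthesis, is downregulated, and 2 samples named WS. What WS stands for is not given in the sources used here. Each sample was hybridised to 1 array, so each group has 2 arrays. The WS samples were pools in which each sample's own extract (185 and 215 µg RNA) was joined by 3 other extracts of 1 µg each, and their labels also carry a drought text of 36 h at an REW of 20 to 30%. The CCR mutant samples were single extracts (144 and 182 µg) with no treatment named. Genotype, pooling and the recorded treatment therefore coincide, and a difference between the groups cannot be assigned to 1 of them. On the 4 arrays 11041, 11038, 11056 and 11056 probe sets reached a log2 value of 4, with medians over all probe sets between 6.55 and 6.60. Over the tested probe sets, Pearson's r across probe sets was 0.981 between the WS arrays, 0.987 between the CCR mutant arrays and 0.965 to 0.978 between arrays of different groups; probe sets are not independent replicates. The median absolute difference did not set the groups apart, at 0.14 between the WS arrays, 0.12 between the CCR mutant arrays and 0.13 to 0.14 between groups. Differences over 1 were found in 269 probe sets between the WS arrays and 229 between the CCR mutant arrays. Between the groups they were found in 231 and 255 for arrays with the same replicate number and in 353 and 369 for the others. Nothing in the labels says that the samples of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

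The first question was whether the targeted gene was lower in the CCR mutant. The probe set of cncr1, the brighter of the 2 CCR probe sets, had a log2 value of 10.56 ± 0.61 in WS and 8.87 ± 0.39 in the CCR mutant (mean ± SD, n = 2 each). The difference was -1.70 (SE 0.38, 95% confidence interval -2.79 to -0.60), a geometric mean in the CCR mutant of 30.9% of that in WS. Both CCR mutant arrays, at 8.59 and 9.14, lay below both WS arrays, at 10.99 and 10.13. The second CCR gene, cncr2, was much dimmer, at 5.47 ± 0.66 in WS and 5.36 ± 0.33 in the CCR mutant (mean ± SD, n = 2 each), a difference of -0.11 (SE 0.39, 95% confidence interval -1.22 to 1.01). With limma, cncr1 had a p of 0.0135 and an adjusted p of 0.68 over all tested probe sets, so it did not pass the threshold. Adjusted over the list alone, that is over both CCR genes, its p was 0.0269. The difference of cncr2 took the other sign without WS replicate 1 (0.36) or without CCR mutant replicate 2 (0.13).

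The other measured genes of monolignol synthesis differed by less than the spread between replicates. PAL1 (phenylalanine ammonia-lyase, the entry step of the pathway) differed by -0.07 (SE 0.14), 4CL (4-coumarate-CoA ligase) by 0.04 (SE 0.25) and CAD2 (cinnamyl alcohol dehydrogenase, the step after CCR) by -0.08 (SE 0.20). None of the 5 genes of the list, the CCR genes included, passed over all tested probe sets or adjusted over the list alone.

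**Figure D1:**
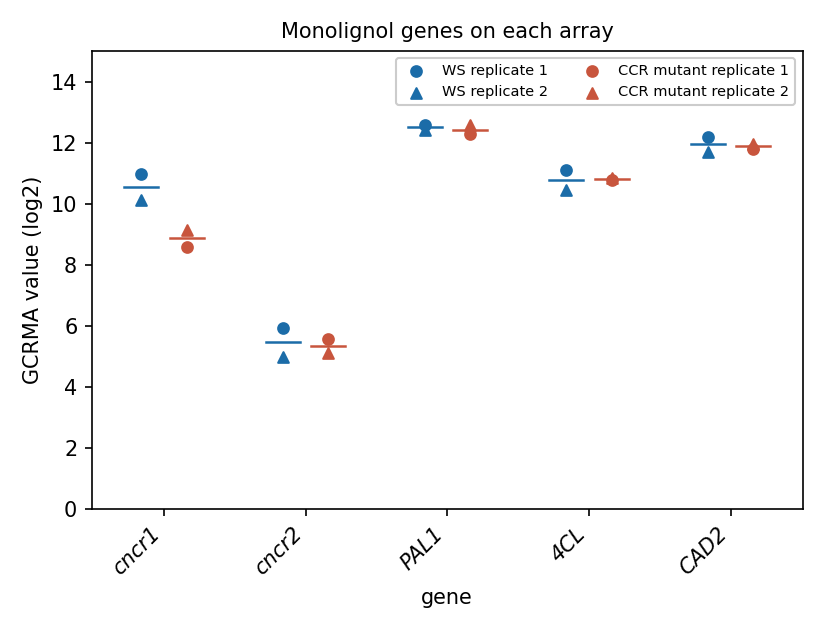
GCRMA values (log2, vertical axis) of the 5 measured monolignol genes on each of the 4 arrays; circles are replicate 1 and triangles replicate 2 of WS (blue) and of the CCR mutant (red), and short lines are group means. The cncr1 values of the CCR mutant arrays, 8.59 and 9.14, lie below those of the WS arrays, 10.99 and 10.13, while the points of the groups overlap for cncr2, PAL1, 4CL and CAD2.

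The next question was which transcripts differed across the whole array. Of 11085 tested probe sets, 17 passed (limma, Benjamini-Hochberg adjusted p under 0.05), of which 9 rose and 8 fell in the CCR mutant. None of the 17 is paired with a gene in the annotation used here, so they are given as probe sets. As measured, the risen probe sets differed by 2.35 to 7.56 on the log2 scale, with a median of 5.46. The sizes of the falls were between 2.42 and 8.18, with a median of 3.33. In 12 of the 17 (8 risen, 4 fallen) the mean of the dimmer group was at most 3.5, near the level of probe sets for reporter genes foreign to maize, of which 65 of 66 stayed at or below 3.43 on every array. In these the size of a change in signal is known only as a lower bound, computed against that reporter level where the dimmer group lay below it. The bound is for signal, since sequence variants at the probes, taken up in the closing section, stay open with the transcript level unchanged. In several of the 12 the dimmer group also varied very little, such as 2.44 and 2.45, or 2.35 on both arrays. That lowers the pooled variance, so their adjusted p rests in part on values near background. Setting values below 4 to 4 leaves such a group no spread at all and does not test this.

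The probe set with the highest lower bound of a rise had log2 values of 2.44 and 2.45 in WS and of 9.74 and 10.26 in the CCR mutant, higher by at least 6.57 (adjusted p = 0.0107). A further probe set had 3.44 and 3.30 in WS against 10.15 and 9.59, at least 86.8-fold higher (adjusted p = 0.0175), and another 3.33 and 3.28 against 9.91 and 9.70, at least 83.0-fold higher (adjusted p = 0.00292). The fall with the highest lower bound went from a mean of 10.86 in WS to 2.69 and 2.67 in the CCR mutant, at least 172-fold lower (adjusted p = 0.00292). The next fall went from 8.84 on both WS arrays to 3.64 and 4.22 in the CCR mutant, a difference of -4.91 (SE 0.23, adjusted p = 0.0369). The identifiers of these 5 probe sets stand beside their points in the plot of differences against level. At an unadjusted p under 0.05 there were 713 probe sets, 243 higher and 470 lower in the CCR mutant, where chance gives 554. The other splits of the arrays gave 643 (replicates 1 against replicates 2) and 248. The groups did not overlap in 36.5% of the tested probe sets, where chance gives 33.3%. With the replicate number as a block in the fit, which the labels neither name nor exclude, 0 probe sets passed. With any 1 of the 4 arrays left out (WS replicate 1, WS replicate 2, CCR mutant replicate 1 or CCR mutant replicate 2) 0 probe sets passed, and with a variance common to all probe sets 212 passed.

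**Figure D2:**
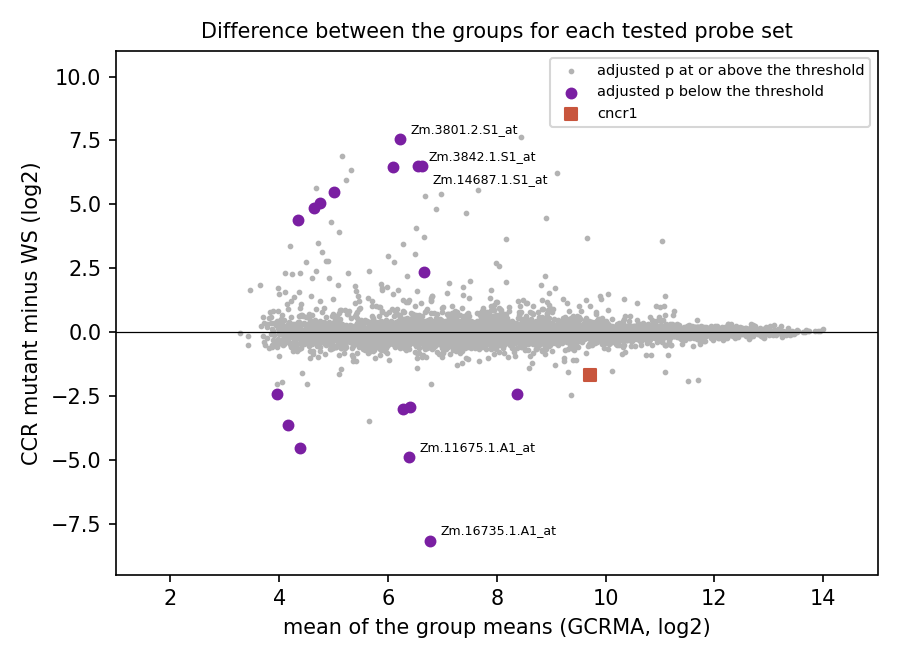
Difference between the groups (CCR mutant minus WS, log2, vertical axis) against the mean of the group means (log2, horizontal axis) for the 11085 tested probe sets. The 17 that passed are purple, with differences from -8.18 to 7.56 and identifiers beside the largest measured rises and falls, and cncr1, at -1.70, is the red square.

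No named gene passed over all tested probe sets, so the 10 named genes with the smallest p are given as values. All 10 had higher values in the CCR mutant. The groups did not overlap for any of them, which the choice by smallest p makes nearly certain. Among them were si1, sts1 and zmm29, which encode B-class MADS-box factors of floral organ identity. The log2 value of si1 was 4.96 ± 0.45 in WS and 8.02 ± 0.42 in the CCR mutant, a difference of 3.06 (SE 0.33). The value of sts1 was 4.51 ± 0.38 against 7.50 ± 0.17, a difference of 2.99 (SE 0.23), and that of zmm29 was 4.57 ± 0.81 against 8.00 ± 0.41, a difference of 3.44 (SE 0.48; SDs with n = 2). Further MADS-box genes among the 10 were zmm6, near background in WS (3.67 and 3.33 against 6.70 and 5.89, difference 2.80), and zmm31 (difference 0.94, SE 0.13). Their limma adjusted p-values were between 0.143 (sts1) and 0.397 (zmm31).

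The other 5 of the 10 belong to different pathways. Asparagine synthetase asn1 differed by 1.27 (SE 0.11), from 5.64 to 6.90, with its second probe set at background. Alternative oxidase aox3 was at 4.41 and 4.13 in the CCR mutant and near background in WS at 2.65; its difference of 1.63 (SE 0.16) became 0.27 with values below 4 set to 4. HP1, a histidine phosphotransfer protein of the cytokinin relay, differed by 1.30 (SE 0.13). The monosaccharide transporter MST1 differed by 0.73 (SE 0.09), and by 0.57 (SE 0.17) on its second probe set. The aquaporin SIP1-2 differed by 1.73 (SE 0.25). Their limma adjusted p-values were between 0.184 (asn1) and 0.422 (SIP1-2).

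The MADS-box genes were put together as a list only after their values had been seen. They made up 5 of these 10 genes and 15 of 735 tested genes with a name; as these 10 prompted the list, no test of it is given. The 15 had a median difference of 0.49, which was 0.16 without WS replicate 2 and 0.90 without WS replicate 1. M7 was at 6.62 and 6.39 in WS and 9.03 and 7.96 in the CCR mutant, and m27, near background in WS, at 3.67 and 2.97 against 5.68 and 4.10, with CCR mutant replicate 1 the highest for both. Among bright members zap1, m4 and m15 differed by 0.49, 0.40 and 0.35, and zmm19, m26 and m20 by -0.20 each. For zap1, m4 and m15 WS replicate 2 was the lowest array, at 7.81, 8.22 and 8.83 against 8.63, 8.75 and 9.22 in WS replicate 1. The median of the 10 members outside the named genes was 0.16, so the list's median rests in part on the genes that prompted it.

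**Figure D3:**
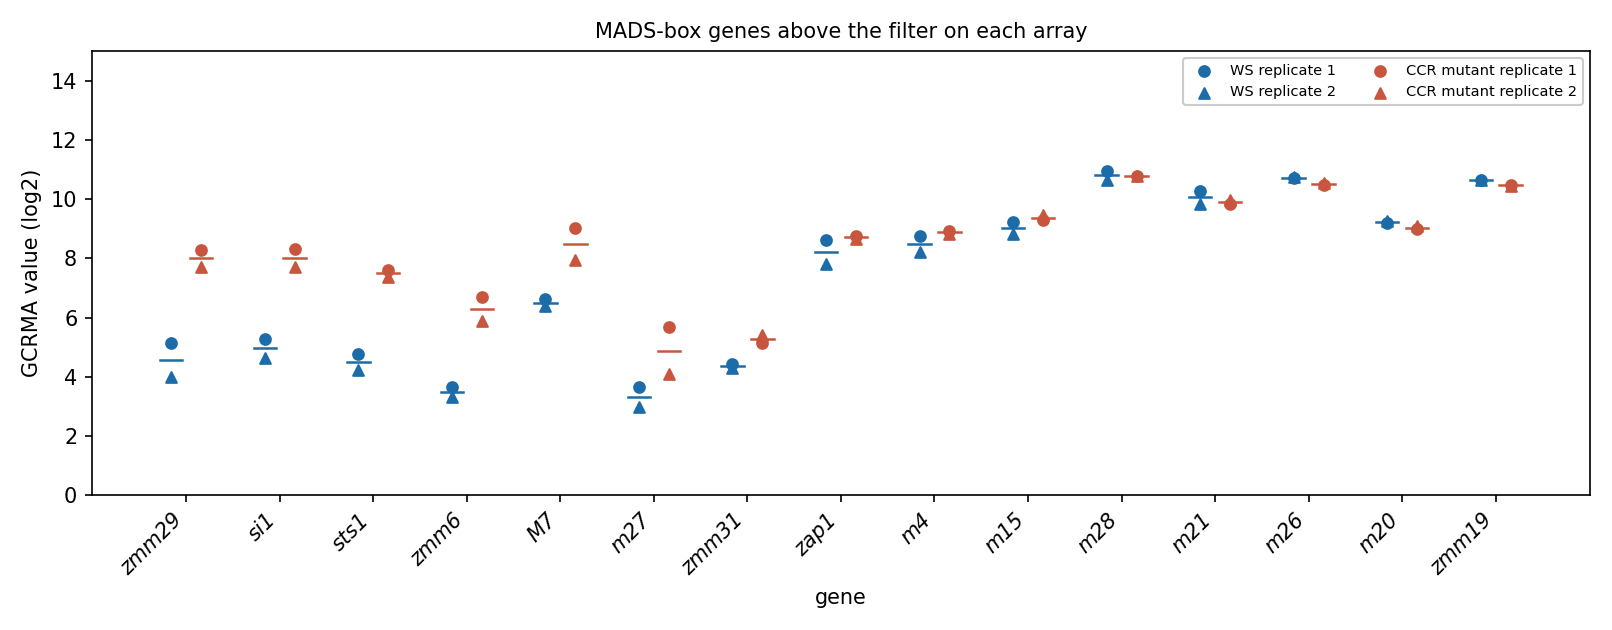
GCRMA values (log2, vertical axis) of the 15 tested MADS-box genes on each of the 4 arrays, ordered by the difference between the groups; circles are replicate 1 and triangles replicate 2 of WS (blue) and the CCR mutant (red), and short lines are group means. The CCR mutant points of zmm29, si1, sts1 and zmm6 lie above the WS points, with differences of 3.44, 3.06, 2.99 and 2.80, while brighter members differ less and in both directions, such as zap1 by 0.49 and zmm19 by -0.20.

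The third question was whether groups of genes fixed in advance shifted together. Of 25 lists, 17 had at least 5 tested genes. Of these, 0 passed with camera (2 at an unadjusted p under 0.05) and 0 with camera and an estimated correlation. With fry, 0 passed in 1 direction and 1 in either direction. An estimated correlation leaves camera only the residual degrees of freedom, 2 here and fewer with an array left out. Few lists could pass in that setting, so a high p there does not show that correlated genes made a list pass. Over the members of all lists, 0 passed over all tested probe sets, and 4 passed adjusted over the list alone: cncr1 among the CCR genes, aox3 (with WS near background), lox1 and opr5. With 1 array left out, the medians of all 17 lists moved by over 1.5 times or changed sign (13 changed sign). So did the differences of 15 of the 32 genes named by the rule fixed in advance, the CCR genes and list leaders included. Of the 10 with the smallest p, 0 did so. These 10 were picked for differences large against their spread, so their steadiness is no check on them. List medians near 0, such as -0.02 for cellulose synthesis and 0.02 for sucrose and starch metabolism, meet this rule after small moves. The count for lists therefore cannot be set against that for genes. The count of passing lists with camera was 2 without WS replicate 1, 1 without WS replicate 2, 1 without CCR mutant replicate 1 and 0 without CCR mutant replicate 2, and none of these lists passed there with an estimated correlation.

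Of the cell wall lists none passed. The 14 tested genes of cellulose synthesis had a median difference of -0.02 (adjusted p = 0.926, 6 higher and 8 lower, 0 passed), and CesA-3, a cellulose synthase, had the smallest p among them with -0.24 (SE 0.11). Hemicellulose and pectin genes had a median of -0.05 over 5 genes (adjusted p = 0.954), with xet1, a xyloglucan endotransglycosylase, at -0.49 (SE 0.51; 0.19 without WS replicate 1 and -1.16 without WS replicate 2). Expansins and wall structural proteins had a median of 0.06 and a mean of -0.03 over 11 genes (adjusted p = 0.915), with expB3, a beta-expansin, at -0.36 (SE 0.17) and expB4 at -0.53 (SE 0.43). The 5 genes of monolignol synthesis had a median of -0.08 and, with cncr1, a mean of -0.38 (adjusted p = 0.915), and the 5 of the shikimate, aromatic amino acid and methyl donor list also had -0.08 (adjusted p = 0.915), with the homocysteine methyltransferase HMT-1 at -0.26 (SE 0.08). The peroxidase PER1, from a lignin polymerisation list with 2 tested genes, differed by -0.29 (SE 0.21), and a2, the single tested flavonoid gene, by 0.17 (SE 0.10).

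In the jasmonate and ethylene list the lipoxygenase gene lox1 had 12.64 ± 0.26 in WS and 10.77 ± 0.57 in the CCR mutant (mean ± SD, n = 2 each), a difference of -1.87 (SE 0.33, limma adjusted p = 0.542), and its second probe set differed by -1.91 (SE 0.28). The oxophytodienoate reductase gene opr5 differed by 0.50 (SE 0.10). The list of 7 genes had a median of 0.19 and a mean of -0.10 (adjusted p = 0.505). In the oxidative stress and detoxification list, 28 genes had a median of -0.05 and a mean of 0.01 (camera adjusted p = 0.949), while fry in either direction gave an adjusted p of 0.0273. The member with the smallest p was aox3 (1.63, SE 0.16), near background in WS at 2.65. How far the fry result rests on aox3 was not tested. Members well above background differed in both directions, such as the alternative oxidase gene Aox (1.91, SE 0.59) and the glutathione transferase gene gst14 (-0.87, SE 0.38).

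The 7 tested drought and abscisic acid response genes had a median difference of 0.05 (adjusted p = 0.915), with asr1 at 0.24 (SE 0.18). The 21 aquaporins had a median of -0.03 and a mean of 0.02, with SIP1-2 in the lead, and the 11 heat shock proteins a median of -0.06 and a mean of 0.18, with hsp18f at 0.56 (SE 0.30); the adjusted p was 0.915 for both lists. The 10 defence genes had a median of -0.04 and a mean of 0.01 (adjusted p = 0.926), with the proteinase inhibitor gene wip1 at 0.45 (SE 0.17). The 21 genes of sucrose and starch metabolism had a median of 0.02 (adjusted p = 0.915), with BMY1, a beta-amylase gene, at 0.93 (SE 0.14). The 19 ribosomal protein genes had a median of -0.04 (adjusted p = 0.915), with RPS10 at -0.21 (SE 0.07). Of the auxin genes 3 were tested, with aic1 at -0.52 (SE 0.17), and of the MYB, NAC and WRKY factors 2, with the MYB gene rs2 at -0.31 (SE 0.08). The list of circadian clock and light signalling matched 0 genes here. Where the median and mean of a list differ in sign, camera's direction was that of the mean for aquaporins, heat shock, oxidative stress and defence genes, and that of the median for expansins and for jasmonate and ethylene.

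Markers of cell types describe the makeup of the tissue. Of 17 genes of meristem and dividing cells, 15 had lower and 2 higher values in the CCR mutant, with a median of -0.30 (camera p = 0.006, adjusted p = 0.102; adjusted p = 0.958 with an estimated correlation). Examples are the cyclin gene cyc3 (-0.57, SE 0.24) and the replication gene MCM7 (-0.41, SE 0.23). The list passed without WS replicate 1 (median -0.26, adjusted p = 0.0021; 0.956 with an estimated correlation) and without CCR mutant replicate 1 (median -0.28, adjusted p = 0.0215; 0.983 with an estimated correlation). Its median shrank to -0.10 without WS replicate 2 (adjusted p = 0.462) and to -0.17 without CCR mutant replicate 2 (adjusted p = 0.734). In WS replicate 2 cyc3 and MCM7 were at 7.70 and 8.34, above 7.08 and 7.89 in WS replicate 1. The homeobox genes KN-1 and lg3 went the other way, at 9.04 and 6.28 in WS replicate 1 and 8.38 and 5.32 in WS replicate 2, against 8.49 and 5.29, and 8.35 and 5.55, in the CCR mutant replicates. Of 16 photosynthetic leaf genes, 14 had higher values in the CCR mutant, with a median of 0.09 (camera p = 0.0271, adjusted p = 0.23; adjusted p = 0.958 with an estimated correlation), and psad1, a photosystem I subunit, at 0.18 (SE 0.13). The leaf median was 0.23 without WS replicate 1 (adjusted p = 0.00029; 0.956 with an estimated correlation) and -0.06 without WS replicate 2. The 9 epidermis and cuticle genes had a median of -0.11 and a mean of 0.03, the sign camera gave (adjusted p = 0.915), with plt2, a lipid transfer protein gene, at 0.26 (SE 0.14). That list passed without WS replicate 2 (median 0.32, adjusted p = 0.00971; 0.951 with an estimated correlation). The 5 genes of secondary wall and xylem had a median of -0.16 (adjusted p = 0.915), with bk2, a COBRA-like gene, at -0.27 (SE 0.17). The phloem gene sut1, a sucrose transporter, differed by -0.45 (SE 0.29), and of 14 seed and pollen genes 2 were tested, with FL1 at -0.17 (SE 0.18; 0.01 without WS replicate 2).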

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

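The rule behind this result, control probe sets in which both CCR mutant arrays exceed both WS arrays by at least 1 on the log2 scale, was set after the control values were seen. One GAPDH control probe set outside the comparisons, AFFX-Zm-gapdh-M_at, met it with a difference of 1.32, at 8.05 and 8.07 in WS and 9.39 and 9.37 in the CCR mutant. The other GAPDH control probe sets differed less, by 0.43 on AFFX-Zm-gapdh-M_s_at, 0.20 on AFFX-Zm_Gapdh_5_f_at, 0.11 on AFFX-Zm_Gapdh_M_f_at and 0.01 on AFFX-Zm_Gapdh_3_s_at, while AFFX-Zm-gapdh-3_at and AFFX-Zm-gapdh-5_at stayed at background on every array.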

How the results depend on the processing

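The settings chosen after seeing the data are values below 4 set to 4, all tested probe sets as list background, lists without their most changed member, an estimated correlation with arrays or probe sets left out, and every test of the MADS-box list. Of 17 passing probe sets, all 17 passed with a variance trend, repeated quantile normalization and median centring. All 17 also passed without _s_at and _x_at probe sets and with a minimum difference of 1. That minimum could drop none, as the smallest of their differences was 2.35 in size. None of their names ends in _s_at or _x_at, so leaving those out could act only through the fit and the adjustment. The arrays were already normalized by quantiles, with medians of 6.55 to 6.60, so normalizing or centring again could change little. The stricter filter left 15, robust variances left 15, and values below 4 set to 4 left 12. Without a filter 9 passed (5 higher, 4 lower), of which 7 were shared with the 17. In a separate limma fit of the probe sets below the filter alone, 60.2% had an unadjusted p under 0.05 at a median difference of 0.03. Bonferroni left 6 (3 higher, 3 lower), ordinary variances 10 (4 higher; 3 shared) and a common variance 212 (153 higher, 59 lower). With 1 array left out the counts were 0 to 0, each lone array being assumed to vary like the other group, at 473 to 976 probe sets with an unadjusted p under 0.05. The replicate block gave 0 (0 higher, 0 lower; lowest adjusted p 0.0574; 774 at an unadjusted p under 0.05), with fewer residual degrees of freedom. The labels do not say that a replicate number is shared; differences of replicate 1 minus 2 in the groups had a Pearson's r of 0.348 and a Spearman's rho of 0.124 across probe sets. Poly-A spikes averaged 7.55 and 8.41 in WS replicates 1 and 2 and 8.28 and 9.16 in those of the CCR mutant. They thus differ by replicate number in both groups, and by group at each replicate number. The 3' minus 5' signal was higher in replicate 1 of both groups for actin (3.46 and 3.16 against 3.36 and 3.06) and EF1a. For GAPDH it did not differ by replicate number (1.69 on both WS arrays, 1.5 on both CCR mutant arrays). Ubiquitin and cyclophilin moved in opposite ways in the groups.

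For cncr1 a common variance gave -1.70 with an adjusted p of 2.93e-08; without 1 array the difference ran from -2.13 to -1.27, and no other setting passed. For cncr2 it ran from -0.57 to 0.36. The count of passing lists was 0 to 2 with 1 array left out, 1 without _s_at and _x_at probe sets (meristem and dividing cells, median -0.30, adjusted p = 0.0338; 0.966 with an estimated correlation), 1 with fry in either direction, and 0 in the others; camera has no robust setting, so that was not run. The cause of these moves was not tested. Of 537 gene values under alternatives 4 changed sign, and of 283 list directions 38, and none of these had passed. A change of filter, variance model, adjustment or replicate block leaves a gene's difference as it is, so most of the 537 could not change sign. All 4 came with 1 array left out. They were cncr2 without WS replicate 1 and without CCR mutant replicate 2, xet1 without WS replicate 1, and FL1 without WS replicate 2. The median of the MADS-box list ran from 0.16 to 0.90 with 1 array left out.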

Other observations

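The tests of cross-hybridisation and of inflorescence tissue, the permutation without zmm6, the demand for at least 5 other probe sets in the test of sequence variants, and the choice of the genes in the next paragraph were made only after the results were seen.

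Several MADS-box probe sets below the filter were above background on 1 array alone. The probe sets of ZMM2 (4.91), M7 (4.71, its second probe set), ZAG3 (4.38), zmm14 (4.19) and M8 (3.98) exceeded 3.5 in CCR mutant replicate 1 and in no other sample, whereas 0 MADS-box probe sets did so in any other sample alone. ZAG1 and zag2, AGAMOUS-related floral genes, lay at background on all 4 arrays, with ZAG1 at 2.35 and 2.33 in WS and 2.39 and 2.38 in the CCR mutant. Of 3 alternative oxidase genes aox1 lay at background on all 4 arrays (2.47 to 2.61), and the other 2 had higher values in the CCR mutant, Aox at 6.76 and 5.59 in WS against 8.62 and 7.54, and aox3 at 2.78 and 2.51 against 4.41 and 4.13. In sugar metabolism the fructokinase gene frk1 had 9.12 and 9.31 in WS against 8.65 and 8.72, a difference of -0.53 (SE 0.10), while frk2 differed by -0.04 (SE 0.08).

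The labels of the WS samples carry a drought text. The drought response genes argue against a stronger drought response in the WS samples than in the CCR mutant samples. The median difference (CCR mutant minus WS) of the 7 tested genes was 0.05, with an SD of 0.14 over the genes. The dehydrin gene dhn1, a marker of water deficit, lay at background on all 4 arrays (2.29 to 2.81), and the 3 dhn2 probe sets differed by 0.05 to 0.12 between the groups. The brightest dhn2 probe set was at 10.72 to 10.78 over the arrays of both groups. A state of the CCR mutant plants that raised the same genes equally stays open, and the labels give no means to test it. No sample is labelled as well watered, and no array shows dhn1 above background, so drought in the WS plants themselves is not decided.

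There were 15 probe sets at or below 3.5 on both arrays of 1 group and at or above 6 on both arrays of the other, 13 higher and 2 lower in the CCR mutant. The other splits of the 4 arrays gave at most 2, and 3 splits are too few for a share under 0.05. Sequence variants at the probes, with the transcript unchanged, stay open: only 2 of the 15 had another tested probe set of the same cluster number, and those differed by a median of 0.40 in the same direction, at 0.98 and -0.19. A stretch of another haplotype around cncr1 also stays open. The 20 tested genes with a name nearest to it in assembly Zm-B73-REFERENCE-NAM-5.0 had a mean absolute difference of 0.38. Random sets had a median of 0.19 (1-sided permutation p = 0.0534), and without zmm6 the permutation p was 0.207. Besides zmm6 (2.80), the 20 include HP1 (1.30), also among the 10 named genes with the smallest p, and ub2 (-0.36). Only 705 tested genes with a name had a position, so the 20 may reach far beyond a local stretch. The genotype is a biological explanation that these data did not test.

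The higher values of MADS-box genes in the CCR mutant do not go with a large difference in RNA integrity. The difference between 3' and 5' signals of 5 control transcripts moved by a median of -0.10 between the groups. For GAPDH (-0.19) and ubiquitin (-0.14) both CCR mutant arrays lay below both WS arrays. Actin moved by -0.10 with overlapping groups, cyclophilin by 0 and EF1a the other way, by 0.095. More inflorescence tissue in the CCR mutant samples stays open: fea2, ub2 and ids1 had a median of -0.31, but 10 of 13 such genes lay below the filter and these 3 were also measured in WS, so a small share of such tissue could be hidden and the sign of that median does not decide. Cross-hybridisation stays open too, with a median of 0.37 over the 12 probe sets of the plain type. Of these zmm6, M7, m27 and zmm31 were higher by 2.80, 1.99, 1.57 and 0.94 as measured, with zmm6 and m27 near background in WS. The genes si1, sts1 and zmm29 are measured only by probe sets whose names end in _a_at. A difference in developmental timing between the groups may be a further explanation, which was not tested.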
